A study of Drosophila melanogaster with 12 samples.

How the data were processed

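The series holds 12 Affymetrix Drosophila arrays of total RNA from fly heads, in 4 groups of 3 arrays. The groups cross a behavioural conditioning with the time after it: non-conditioned and conditioned flies, at 0 h and at 24 h. The labels carry the word OR, which is not expanded there, and they state neither the kind of conditioning nor the sex of the flies. Per the labels, both other arrays of the group conditioned at 0 h and 1 array of the group conditioned at 24 h are biological duplicates of a first array of their group. Nothing of the kind is said for the remaining arrays, so p-values measure the spread between these samples, which may be technical in part. Replicates are numbered in the order of the series, and these numbers pair no arrays across groups.

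The deposited table gives 1 linear intensity per probe set and array for 18952 probe sets. The program, background correction and filters used by the authors are not given in the sources used here. The 2%-trimmed mean of the deposited intensities was 150 on every array, so the arrays had been scaled to a common level before deposit. Array medians lay between 19.9 and 21.8. For arrays, the number of arrays limits the precision. No column of the table was left without a sample.

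Intensities were put on a log2 scale after adding 16, so that fold changes of dim probe sets are understated. The medians of the 12 arrays ranged over 0.075 on this scale, below the limit of 0.2 set for quantile normalization, and the values were used as deposited. The 183 control probe sets were removed, and the upper 60% by mean over the 12 arrays were kept, which left 11261 probe sets above a mean intensity of 8.05. Gene names came from the platform annotation, with symbols updated through the RefSeq gene table of assembly Release 6 plus ISO1 MT, in which 13544 of 13647 probe sets with 1 symbol had their gene identifier. Besides those, 402 probe sets had several symbols and 4720 had none, and none of these was named.

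Each probe set was fitted with limma 3.58.1 in R 4.3.3, with 4 group means and a term for the form of the sample title, and eBayes with a mean-variance trend. The titles have 2 forms: 8 arrays, 2 per group, have a # in the title and 4 arrays, 1 per group, do not. Whether the forms mark separate rounds of work is not stated. The fit left 7 residual degrees of freedom, and the median total after moderation was 15.7. The 6 comparisons were conditioned against non-conditioned at each time, the difference between these (interaction), 24 h against 0 h in each arm, and conditioning averaged over both times. All p-values are two-sided, and the threshold was a Benjamini-Hochberg adjusted p of 0.05 over all probe sets of a comparison.

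For each gene, the brightest probe set was used to test 25 gene lists with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The lists covered nervous system functions, the circadian clock, immunity, stress, metabolism, cuticle, sensory proteins and markers of female, male, muscle, gut and fat body tissue. The same lists were tested with an estimated correlation and with fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. No list passed with an estimated correlation in any comparison. Members were also counted with p-values adjusted over the list alone.

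The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. For each pairwise comparison and direction, that rule names the 10 probe sets with 1 symbol and the largest change past the threshold whose groups do not overlap, filled up by the lowest p where fewer qualify. The interaction and the averaged effect have 5 per direction. Up to 4 members of each list were added, those of lowest p where the list passed and otherwise those past the threshold, together with per, tim, Hr38, EcR, rut, dnc, CrebB, fru and Yp1. The fit was tested on simulated data with 200 of 11261 probe sets changed. For conditioned against non-conditioned at 0 h, it recovered 40.3% of changes of 0.3, 73.1% of changes of 0.5 and 97.0% of changes of 1 on the log2 scale. At 24 h these shares were 25.4%, 64.2% and 93.9%. False calls in the simulation at 0 h were 12, or 7.9% of all calls and above the 5% aimed at, against 3.2% at 24 h, 2.3% between times without conditioning and 3.2% after it. The simulated noise was normal and independent between probe sets and arrays. Correlated genes and single deviating arrays were thus left out, and the shares need not hold for the real arrays. A single data set was simulated per comparison. Differences between comparisons in these shares therefore cannot be told from the spread of single draws.

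Alternatives covered the title term, the # arrays alone, quantile normalization, median centring, offsets of 1 and 64, no filter, the upper 40%, eBayes without trend, array weights, fits of single comparisons, other thresholds and each array left out. A fit without 3 arrays that carried yolk protein signal was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.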

Results

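Transcript levels in fly heads were measured on 12 arrays, 3 for each combination of conditioning (non-conditioned or conditioned) and time after it (0 h or 24 h). The labels describe the treatment as a behavioural stimulus. All arrays had the same trimmed mean intensity, and between 32.5% and 33.0% of their probe sets lay above an intensity of 100. Correlations of log2 values ran from 0.991 to 0.995 within groups and from 0.987 to 0.995 between groups, and no 2 arrays held identical values. The first principal component, with 25.3% of the variance, separated the times: the 0 h arrays lay between -12.98 and -4.13 and the 24 h arrays between 6.08 and 11.46. At 0 h it also separated non-conditioned arrays, at -10.62 or below, from conditioned arrays, at -5.83 or above.

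**Figure D1:**
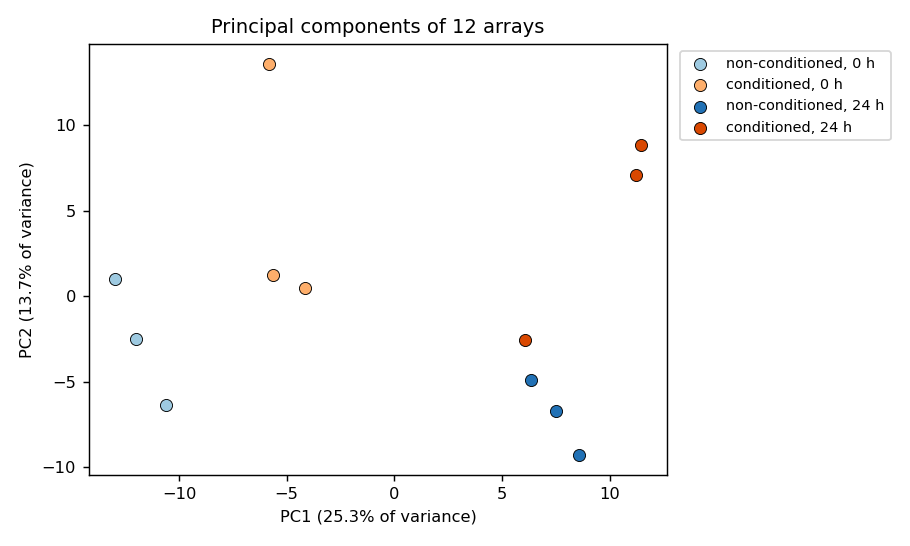
The 12 arrays on the first and second principal components of the log2 values, 1 point per array coloured by group. The 0 h arrays lie to the left and the 24 h arrays to the right, with conditioned 0 h arrays between -5.83 and -4.13 on the first component.

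Transcripts of the yolk protein genes, which are typical of female flies, were high in 3 conditioned arrays and low in the other 9. In replicate 3 at 0 h and replicates 1 and 2 at 24 h, Yp1 had intensities of 4530, 5030 and 6650, against 1.07 to 20.8 elsewhere. Yp2 lay between 1860 and 5500 in these arrays and at 26.4 or below in the others, and Yp3 between 2230 and 5560 against 179 to 245. The same 3 arrays had the highest values on the second principal component, 13.62, 7.11 and 8.88. That component was computed with the yolk protein probe sets included, so it is not separate evidence. Fits without them kept 2 conditioned arrays at 0 h and 1 at 24 h, assumed to vary like the other groups, so a call can be lost to the smaller groups alone and list means are given beside lost list calls. Accessory gland transcripts, which are typical of males, stood out in non-conditioned replicate 3 at 0 h. Of 27 male list members on the array, 10 exceeded an intensity of 30 and 2 times the next array, all in that replicate, among them Acp98AB at 351 against 4.9 and Acp36DE at 128 against 12.4. Several gene lists named below missed the threshold without this replicate. Whether its accessory gland transcripts mark RNA of other tissue that moved those lists was not tested.

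**Figure D2:**
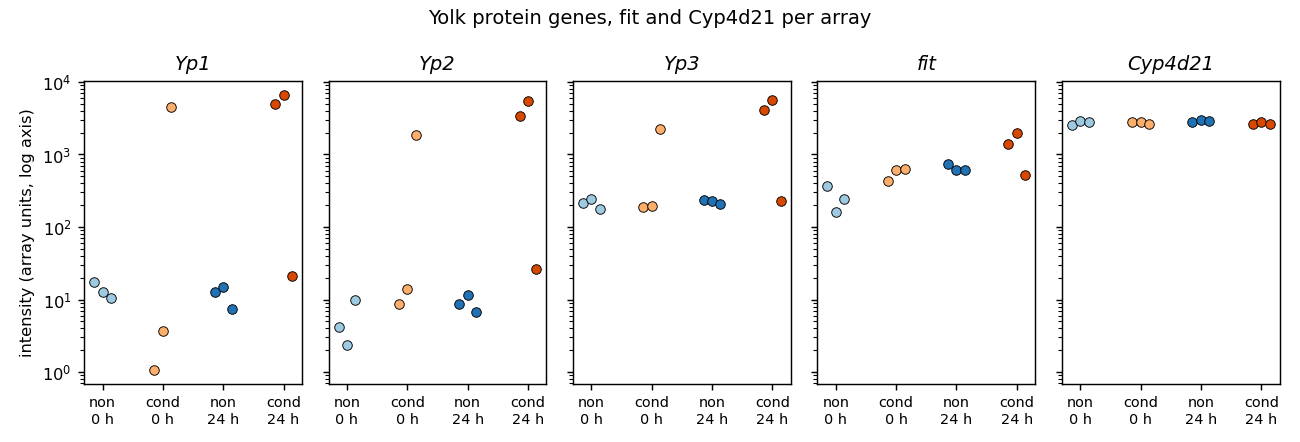
Intensity (log axis, array units) of Yp1, Yp2, Yp3, the female-biased fit and the male-biased Cyp4d21 in each array, 1 point per array, by group. Yp1 reaches 4530 to 6650 in 3 conditioned arrays and stays at 20.8 or below in the other 9.

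The first comparison asks which transcripts differed immediately after conditioning. In conditioned heads at 0 h, 33 probe sets were higher and 32 lower than in non-conditioned heads. Of these probe sets, 20 and 14 also passed in the same direction between the times without conditioning, which uses the same non-conditioned arrays. There the non-conditioned 0 h group can be the one that stands apart, as in CG15199, at 85.2 to 95.7 in non-conditioned heads at 24 h. Between the times after conditioning, 8 and 9 passed in the opposite direction. Rises and falls are given relative to the non-conditioned 0 h arrays. The clearest rises were in CG15199, from 42.2 ± 3.61 to 101 ± 19.0 (mean ± SD, n = 3), and in Irp-1B, a cytosolic aconitase related to iron regulatory proteins, from 706 ± 12.1 to 1089 ± 138. Their log2 changes were 0.99 ± 0.11 (SE, adjusted p = 0.00138) and 0.61 ± 0.07 (adjusted p = 0.00202). CG10621 rose by 0.58 (adjusted p = 0.00351), the glucuronosyltransferase gene Ugt37A3 by 0.92 (0.0088) and the cathepsin gene CtsL3 by 0.55 (0.00658). Nepl4, Or1a, atk, CG4577 and CG5958 also rose, by 0.49 to 0.82, although Nepl4 and Or1a were dim, at 22.4 and 12.7 in conditioned heads. In non-conditioned heads their arrays lay at 2 to 8.8 and at 1.2 to 1.3, so the size of these changes depends on the offset of 16.

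The triglyceride lipase gene bmm fell by 0.55 (adjusted p = 0.00658), from 636 ± 70.0 to 429 ± 52.3, and tobi, an alpha-glucosidase gene under insulin control, fell by 0.49 (0.0163). The stress-induced TotC fell by 1.68 (0.0157), from 1781 ± 784 to 527 ± 178. CG17646 fell by 0.60 (0.00377), and the clock repressor gene cwo fell by 0.49 (0.00658), from 520.3 ± 39.6 to 365 ± 9.92. Diedel had the largest change, -2.74 ± 0.58 (adjusted p = 0.0474), but its non-conditioned mean of 322 had an SD of 380. The others named were phu, Dr, CG13116 and CG32425, at -0.95 to -0.46, and of the 3 probe sets of CG32425 only this probe set passed, the others lying at -0.11 and 0.02. Yp1 and the learning genes rut and dnc did not pass, at 1.97 ± 1.82, 0.09 ± 0.09 and -0.02 ± 0.08, nor did fru at 0.04, CrebB at -0.06, EcR at -0.15, per at -0.17 or Hr38 at 0.09.

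**Figure D3:**
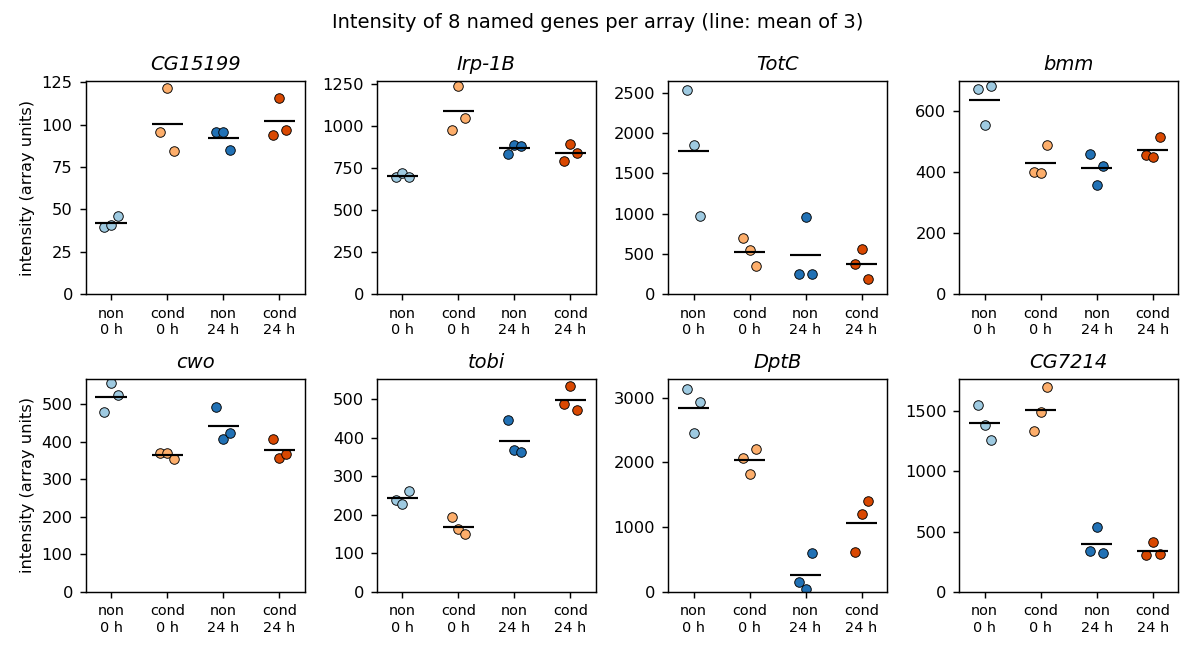
Intensity (array units, axes from 0) of 8 named genes in the 4 groups, 1 point per array with a line at the mean of 3. In CG15199 and Irp-1B every conditioned array at 0 h lies above every non-conditioned array at 0 h, and in TotC, bmm, cwo and tobi every one lies below.

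Of the 25 gene lists, 10 lay lower in conditioned heads at 0 h with the preset correlation and none with an estimated correlation. Antimicrobial and immune genes lay lower (adjusted p = 0.000546, and adjusted p = 0.296 with an estimated correlation): of 23 measured members, the NF-kappaB gene Rel fell by 0.35 (adjusted p = 0.012), 2 fell adjusted over the list alone, and PGRP-SC2, edin and Def had values of -1.32, -1.63 and -0.60 without passing. Of 22 clock genes (adjusted p = 0.0109, and adjusted p = 0.296 with an estimated correlation) 3 fell, namely cwo, vri by 0.30 (0.0486) and the ecdysteroid hydroxylase gene Cyp18a1 by 0.41 (0.0177), or 5 adjusted over the list alone, while tim had a value of -0.22. Among 13 digestive enzyme genes (0.00913, and adjusted p = 0.296 with an estimated correlation), tobi fell, or 3 adjusted over the list alone, with Mal-A1 at -0.45. Among 19 activity-regulated genes (0.0441, and adjusted p = 0.355 with an estimated correlation), cbt fell by 0.41 (0.017), or 3 fell and 1 rose adjusted over the list alone, and Arc1 had a value of -0.29. Of 19 head fat body genes (0.0441, and adjusted p = 0.355 with an estimated correlation) bmm fell, with 3 lower and 3 higher adjusted over the list alone. Among 91 odorant binding and chemosensory genes (0.042, and adjusted p = 0.355 with an estimated correlation), Obp28a fell by 0.35 (0.0271) and Or1a rose, or 2 fell and 1 rose adjusted over the list alone. Without non-conditioned 0 h replicate 3, the array with accessory gland transcripts, the fat body and chemosensory lists missed the threshold (0.453 and 0.191). Without conditioned 0 h replicate 2 the activity-regulated list did (0.187). Without the 3 arrays with yolk signal, 2 lists passed, the immune and ribosomal ones, and the clock and digestive lists both had an adjusted p of 0.0709, their means going from -0.076 to -0.062 and from -0.132 to -0.096.

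Without a single member past the threshold, 4 more lists lay lower at 0 h. They were 35 ribosomal protein genes (adjusted p = 0.000546, and adjusted p = 0.494 with an estimated correlation, 0 members adjusted over the list alone), 24 muscle genes (0.0468, and adjusted p = 0.438 with an estimated correlation, 0 alone) and 62 oxidative phosphorylation genes (0.0468, and adjusted p = 0.689 with an estimated correlation, 0 alone). The last turned to the other direction under quantile normalization, with an adjusted p of 0.502. Muscle and oxidative phosphorylation genes missed the threshold without non-conditioned 0 h replicate 3, the array with accessory gland transcripts (0.585 and 0.222). The serine protease inhibitor list (0.0468, and adjusted p = 0.396 with an estimated correlation) had 2 of 16 members lower adjusted over the list alone and missed it without conditioned 0 h replicate 1 (0.178). Under quantile normalization only the immune list passed, with an adjusted p of 0.0117. Values of RpS21 and Prm were -0.25 and -0.18, and of ND-B12 and Spn88Eb -0.32 and -0.30, none past the threshold. Without the 3 arrays with yolk signal, list means at 0 h moved both ways. They went from -0.063 to -0.065 (activity-regulated), -0.064 to -0.067 (serine protease inhibitor) and -0.028 to -0.043 (oxidative phosphorylation). They shrank from -0.041 to -0.023 (chemosensory), -0.038 to -0.009 (fat body) and -0.051 to -0.024 (muscle).

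The nervous system lists did not pass at 0 h: learning and memory (adjusted p = 0.367, 0 of 26 members), monoamine (0.251, 0 of 28), neuropeptide (0.811, 0 of 24), pan neuronal (0.924, 0 of 33), glial (0.315, 0 of 19) and phototransduction genes (0.244, 0 of 26). Adjusted over the list alone, 1 neuropeptide gene was higher and 1 lower and 1 pan neuronal gene was higher. For neuropeptide genes the median was -0.016 and the mean 0.006, with the test pointing down, and for pan neuronal genes both were 0.008 with the test also down. Female (0.0956), male (0.122) and sex determination lists (0.251) did not pass either, nor did nutrient and insulin (0.109, with bmm and tobi lower), cuticle (0.15), heat shock and stress (0.176, with TotC lower), ecdysone (0.258, with Cyp18a1 lower), proteasome (0.315) and detoxification genes (0.811). The last list held 3 members that rose, Ugt37A3, Ugt35C1 by 0.48 and Cyp6w1 by 0.35, and Cyp18a1, which fell, or 7 and 2 adjusted over the list alone.

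At 0 h, 1976 probe sets (17.5%) had groups that did not overlap, where chance gives 10% for 3 against 3, and 4 of the 65 changed by over 2-fold. The 65 became 14 or 30 without conditioned 0 h replicate 2 or 1, 26 without non-conditioned 0 h replicate 3, 150 without non-conditioned 24 h replicate 1, and 17 both in the # arrays alone and without the 3 arrays with yolk signal. They became 8 without the variance trend and 28 without a filter, and median centring called 58 higher and 27 lower. Of 27 named genes past the threshold, CG15199, Irp-1B, CG10621, CtsL3, CG17646 and cwo passed with every array left out in turn, and the other 21 missed it at least once.

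The second comparison asks which transcripts differed 24 h after conditioning. At 24 h, limma called 0 probe sets between conditioned and non-conditioned heads, against 488 with an unadjusted p under 0.05, and 10.5% of probe sets had groups that did not overlap where chance gives 10%. The lowest adjusted p, 0.108, belonged to DptB, which encodes an antibacterial peptide, and to a single probe set of lola, a transcription factor gene with several probe sets. DptB averaged 1069 ± 411 in conditioned and 264 ± 293 in non-conditioned heads, a log2 difference of 2.47 ± 0.42, and lola 136 ± 19.6 against 189 ± 18.1, a difference of -0.44 ± 0.07. The other genes named had an adjusted p of 0.999, with values such as 0.34 for tobi, 0.35 for the neuropeptide gene Dh31, 0.44 for CG1663, -0.66 for CCHa1-R, -0.32 for the integrin gene mys and -0.25 for tim. The always named genes did not pass, with per at -0.30, EcR at 0.34, fru at -0.23, CrebB at -0.20, Hr38 and rut at -0.08 and dnc at -0.02.

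At 24 h, 5 lists passed with the preset correlation and none with an estimated correlation, and no member of any list passed over all probe sets. Antimicrobial and immune genes lay higher (adjusted p = 0.00119, and adjusted p = 0.312 with an estimated correlation), with 3 of 23 members past the threshold adjusted over the list alone. DptB, Mtk and edin had values of 2.47, 0.79 and 2.01, the last against dim non-conditioned arrays (5.4, 6.3 and 43.3). The list missed the threshold without non-conditioned 24 h replicate 2 (adjusted p = 0.0992) and without the 3 arrays with yolk signal (0.0738), where its mean went from 0.339 to 0.266. Clock genes lay lower (0.00472, and adjusted p = 0.312 with an estimated correlation, 1 of 22 alone), as did muscle genes (0.00472, and adjusted p = 0.742 with an estimated correlation, 0 of 24 alone) and oxidative phosphorylation genes (0.00302, and adjusted p = 0.938 with an estimated correlation, 0 of 62 alone). Clock genes missed it without non-conditioned 24 h replicate 1 (0.0553) or the 3 arrays (0.131, mean -0.062 to -0.043), and muscle genes without conditioned 24 h replicate 3 (0.45). Oxidative phosphorylation genes missed it without conditioned 24 h replicate 1 (0.236), and pointed up without non-conditioned 24 h replicate 2 (0.227). Female transcripts lay higher (0.00617, and adjusted p = 0.734 with an estimated correlation, 4 of 6 alone), with values of 5.22 for Yp2, 5.29 for Yp1, 2.88 for Yp3 and 0.77 for fit. These stem from replicates 1 and 2, whose yolk protein values are given above, and the list had an adjusted p of 0.111 without conditioned 24 h replicate 1 and 0.535 without the 3 arrays, its mean going from 2.274 to 0.066. The count of 0 became 8 in the # arrays alone, where both conditioned 24 h arrays carry yolk signal, 2 without the 3 arrays, and 6, 2, 2 and 1 without conditioned 24 h replicate 3 or 1, non-conditioned 24 h replicate 3 or non-conditioned 0 h replicate 3.

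Whether conditioning acted differently at the 2 times was tested as an interaction. The fit called 0 probe sets with limma, against 810 with an unadjusted p under 0.05 and 10 with an adjusted p under 0.10. The lowest adjusted p, 0.0512, was shared by tobi, bmm and Irp-1B. The conditioning effect of tobi was higher at 24 h than at 0 h by 0.83 ± 0.13 and that of bmm by 0.75 ± 0.12, and that of Irp-1B differed by -0.65 ± 0.11. CG15199 had a value of -0.87 (adjusted p = 0.0664), CG7408 of 1.03 and CG1628 of -0.54. For lola and Pde1c, at -0.53 and -0.54, other probe sets of the gene did not all share the sign in the pairwise comparisons. Among the 33 probe sets higher at 0 h, the median conditioning effect went from 0.43 at 0 h to 0.04 at 24 h and 23 kept their sign, and among the 32 lower ones it went from -0.41 to -0.02 and 20 kept it. The probe sets were chosen for their 0 h values, which by itself favours a smaller value at 24 h.

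Antimicrobial and immune genes had the lowest p-value of the lists in this test (adjusted p = 7.31e-08, and adjusted p = 0.0957 with an estimated correlation). Over 23 members the mean interaction was 0.613 and the median 0.179 on the log2 scale, 0 members passed over all probe sets and 6 passed adjusted over the list alone. The values were 2.94 ± 0.60 for DptB, 1.97 ± 0.42 for PGRP-SC2, 3.64 ± 0.88 for edin and 0.37 ± 0.09 for Rel. Digestive enzyme genes also differed (adjusted p = 0.00368, and adjusted p = 0.2 with an estimated correlation), with 1 of 13 members past the threshold adjusted over the list alone and values of 0.83 for tobi and 0.46 for Lip4. This list missed the threshold without a filter (adjusted p = 0.0996) and without the 3 arrays with yolk signal (0.487, mean 0.183 to 0.076). The count of 0 became 6 in the # arrays alone, 3 without those 3 arrays and 21 with array weights. It was 8 without non-conditioned 0 h replicate 3, 6 without non-conditioned 24 h replicate 1, 4 without conditioned 0 h replicate 3, 3 without non-conditioned 0 h replicate 2, and 2 without conditioned 0 h replicate 1, conditioned 24 h replicate 1 or non-conditioned 24 h replicate 3.

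The largest sets of differences lay between the times. In non-conditioned flies, 355 probe sets were higher and 233 lower at 24 h than at 0 h. Genes that rose included smp-30 from 332 ± 22.5 to 811 ± 48.4 (log2 change 1.25 ± 0.07, adjusted p = 4.92e-08), CG9377 by 1.38 and fit, a gene of the fat body around the brain, by 1.35 (adjusted p = 0.0199). CG10621, Ugt37A3, CG9416, CG31075, CG7997, Pepck2 and CG15199 rose by 0.89 to 1.02. Among the genes named, DptB and edin fell most: DptB from 2840 ± 349 to 264 ± 293 (-3.94 ± 0.42, adjusted p = 3.35e-05) and edin at -3.59. Other antimicrobial peptide genes fell less, with Def at -2.12, Mtk at -1.56 and Drs at -1.42. At 24 h edin and Def were dim, at 5.4 to 43.3 and 2.6 to 12.5. TotC, Diedel and CG3348 fell too, at -2.02, -2.61 and -2.33, as did CG7214, at -1.80 (adjusted p = 2.18e-06), and CG42807, at -1.41. This comparison shares its 0 h arrays with the first one, so chance values of those arrays enter both.

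Of 23 immune genes, 10 fell and none rose between 0 h and 24 h without conditioning, or 12 and 1 adjusted over the list alone, among them Rel by 0.50 (list adjusted p = 3.74e-08, and adjusted p = 0.102 with an estimated correlation). Of 24 muscle genes, 11 fell, such as Mlc2 by 0.43, Tm2 by 0.38 and Act87E by 0.37, or 14 adjusted over the list alone (4.36e-10, and adjusted p = 0.122 with an estimated correlation). Zasp66 fell by 0.30 on 1 probe set and 0.32 on another, while another had a value of 0.03. Of 120 cytochrome P450, glutathione transferase and glucuronosyltransferase genes, 17 rose and 2 fell, or 31 and 3 adjusted over the list alone, with Cyp4ac1 up by 0.87, Ugt35C1 by 0.81, Cyp6t1 by 0.67 and Cyp4ac2 by 0.65 (3.15e-05, and adjusted p = 0.185 with an estimated correlation). Of 28 nutrient and insulin genes, 4 rose and 1 fell, or 7 and 1 adjusted over the list alone (0.0313, and adjusted p = 0.278 with an estimated correlation). The gluconeogenic Pepck2 rose by 0.93, tobi by 0.65 and the insulin-like peptide gene Ilp5 by 0.51, while bmm fell by 0.61. This list missed the threshold without non-conditioned 24 h replicate 1 (0.0994).

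Oxidative phosphorylation genes lay lower (1.08e-09, and adjusted p = 0.350 with an estimated correlation), with ATPsyndelta down by 0.30, the single member of 62 past the threshold, also adjusted over the list alone. Ribosomal protein genes lay lower too (9.65e-05, and adjusted p = 0.558 with an estimated correlation, 0 of 35 past the threshold, also adjusted over the list alone), but had an adjusted p of 0.921 under quantile normalization and 0.333 without non-conditioned 24 h replicate 1. Proteasome genes lay higher (0.00244, and adjusted p = 0.379 with an estimated correlation, 0 of 27, also adjusted over the list alone) and missed the threshold without non-conditioned 0 h replicate 3 (0.0999). In the heat shock and stress list (0.0313, and adjusted p = 0.193 with an estimated correlation) TotC fell, or 2 fell and 1 rose adjusted over the list alone, and the list missed the threshold without non-conditioned 24 h replicate 1 (0.0825). In the serine protease inhibitor list (0.0313, and adjusted p = 0.325 with an estimated correlation) Spn27A fell by 0.40 and Spn42Da rose by 0.25 on 1 probe set, with -0.03 on another, or 2 fell and 1 rose adjusted over the list alone. It missed the threshold without the same array (0.12). In lists that did not pass, 2 of 22 clock genes fell and 2 rose, with tim down by 0.46 and the cryptochrome gene cry up by 0.29. Of 19 activity-regulated genes, 5 fell and 1 rose. The genes cbt, CG14186, Arc1, Jra and Hr38 fell by 0.65, 0.46, 0.32, 0.32 and 0.58. The cuticle gene Cpr97Eb fell by 1.04. Sxl fell by 0.30 on 1 probe set, with 0.06 and 0.05 on others.

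In the # arrays alone, the 588 probe sets became 246, and they became 297 without non-conditioned 24 h replicate 3, 342 without the variance trend and 291 with only the groups compared. Of 60 named genes past the threshold, 44 passed with every array left out in turn. Groups did not overlap for 2158 probe sets (19.2%), where chance gives 10%.

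In conditioned flies, 304 probe sets were higher and 222 lower at 24 h than at 0 h. tobi rose from 169 ± 23.1 to 498 ± 32.0, by 1.48 ± 0.09 (adjusted p = 8.42e-08). CG7997 rose by 1.04, Had1 by 0.96, Cyp4ac1 by 0.96, smp-30 by 0.91 and the prophenoloxidase gene PPO1 by 0.91, and CG31075, CG32444, CG6733 and CG9377 by 0.89 to 0.97. CG7214 fell from 1509 ± 181 to 342 ± 59.2, by 2.10 ± 0.15 (adjusted p = 4.01e-07). CG3348 fell by 1.58, CG11458 by 1.11, CG14022, CG8736 and CG7203 by 1.00 to 1.06, Cpr97Eb by 0.98, CG4000 by 0.93, Sid by 0.88 and CG42807 by 0.86. The clock gene tim fell by 0.48 and the activity-regulated nuclear receptor gene Hr38 by 0.76. Of 22 clock genes 2 fell and 1 rose, and of 19 activity-regulated genes 3 fell and 2 rose. The ecdysone receptor gene EcR rose by 0.49 (adjusted p = 0.0371), with a value of 0.08 without the 3 arrays with yolk signal.

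Of 24 muscle genes, 10 fell, or 15 adjusted over the list alone (list adjusted p = 1.41e-10, and adjusted p = 0.112 with an estimated correlation). Mlc1 fell by 0.52, Tm2 by 0.35 and the troponin T gene, whose symbol is up, fell by 0.35. Zasp66 fell by 0.37 and 0.41 on 2 probe sets and had a value of 0.32 on another. Of 120 detoxification genes, 18 rose and 2 fell, or 34 and 6 adjusted over the list alone, with Cyp6d2 up by 0.85 and Cyp28d1 by 0.43 (3.88e-08, and adjusted p = 0.112 with an estimated correlation). Of 28 nutrient and insulin genes, tobi, fbp by 0.42, the adipokinetic hormone receptor gene AkhR by 0.41 and another member rose and Lk6 fell by 0.31, or 6 and 1 adjusted over the list alone (0.0003, and adjusted p = 0.139 with an estimated correlation). Without the 3 arrays with yolk signal the list had an adjusted p of 0.0591 and a mean of 0.13, against 0.156. Oxidative phosphorylation genes lay lower (1.78e-10, and adjusted p = 0.501 with an estimated correlation), with SdhB and ND-ACP the 2 of 62 members that fell, by 0.21 and 0.23, or 20 adjusted over the list alone. Proteasome genes lay higher (5.48e-07, and adjusted p = 0.341 with an estimated correlation), with Prosalpha4 up by 0.27 the single member of 27 past the threshold, also adjusted over the list alone. No immune gene of 23 passed, either over all probe sets or adjusted over the list alone (list adjusted p = 0.353), against 10 in non-conditioned flies, and the difference is the interaction given above. Spn42Da rose by 0.34 on 1 probe set with -0.07 on another.

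These arrays include the 3 with yolk protein signal, and without them the 526 probe sets became 18, with a single conditioned 24 h array left. They became 151 in the # arrays alone, 235 without the variance trend, 334 without a filter, 976 with array weights, 1095 with only the groups compared, 227 to 342 without any 1 of the 6 conditioned arrays, and 37 of 59 named genes past the threshold passed with every array left out. Groups did not overlap for 3168 probe sets (28.1%), where chance gives 10%.

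Changes over 24 h were compared between the arms, which share no arrays but take the spread of each probe set from the same fit. Of the probe sets past the threshold in either arm, 162 were higher in both, where independent lists would share 9.58, and 95 were lower in both, against 4.59. A spread estimated too low favours a call in both arms, so the lists are not independent and these reference numbers can be too low. Among all 856 probe sets past the threshold in either arm, 785 (91.7%) had the same sign, and 1 passed in opposite directions. Across all tested probe sets, which are not independent replicates, the log2 changes had a Pearson correlation of 0.460 and a Spearman correlation of 0.375. The genes tobi, smp-30, CG7997, CG31075, CG9377, Cyp4ac1 and Ilp5 rose in both arms, and CG7214, CG3348, Cpr97Eb, tim, Hr38 and CG42807 fell in both.

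**Figure D4:**
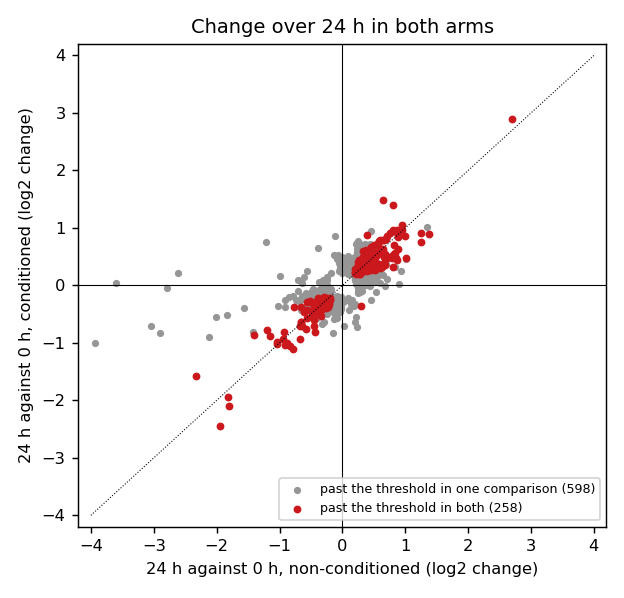
Log2 change from 0 h to 24 h in non-conditioned (x) and conditioned flies (y) for the 856 probe sets past the threshold in either arm, 1 point each, with the line of equal change dotted. Red points passed in both arms, and 785 of the 856 have the same sign in both.

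Averaged over both times, 10 probe sets were higher and 3 lower in conditioned heads. Ugt37A3 rose by 0.64 ± 0.10 (adjusted p = 0.0257), CG15199 by 0.56 (0.0195), Lst by 0.31, CG10621 by 0.31 and CG9436 by 0.24. Such an average need not stand for an effect at both times. At 24 h, conditioned and non-conditioned arrays overlapped for CG15199 (94 to 115.9 against 85.2 to 95.7) and CG10621 (625.5 to 648.7 against 588.1 to 638.9). They also overlapped for Lst, CG9436 and the 3 genes that fell, which are named next. Of the genes named for this average, only Ugt37A3 had arrays that did not overlap (57.4 to 75.7 against 44.9 to 49.7). Over all probe sets, 10.5% had groups that did not overlap at 24 h, where chance gives 10%. The 3 that fell were the homeobox gene Dr by 0.55 (0.0321), cwo by 0.35 (0.0195) and the transcriptional repressor gene hry by 0.35 (0.0257). Clock genes lay lower as a list (adjusted p = 0.000698, and adjusted p = 0.258 with an estimated correlation), with 1 of 22 past the threshold, or 7 lower and 1 higher adjusted over the list alone. Ribosomal protein (0.000743, and adjusted p = 0.535 with an estimated correlation, 1 of 35 alone), oxidative phosphorylation (0.000906, and adjusted p = 0.535 with an estimated correlation, 0 of 62 alone), muscle (0.0013, and adjusted p = 0.396 with an estimated correlation, 0 of 24 alone), activity-regulated (0.0219, and adjusted p = 0.396 with an estimated correlation, 1 of 19 alone) and fat body genes (0.0427, and adjusted p = 0.396 with an estimated correlation, 3 lower and 1 higher of 19 alone) also lay lower. Without non-conditioned 24 h replicate 2 the ribosomal and oxidative phosphorylation lists both had an adjusted p of 0.481. Without non-conditioned 0 h replicate 3, the array with accessory gland transcripts, the muscle and fat body lists had 0.0649 and 0.295. The mean of the fat body list went from -0.014 to -0.034 without the 3 arrays with yolk signal. The activity-regulated list had 0.119 without conditioned 0 h replicate 2, and under quantile normalization the ribosomal and oxidative phosphorylation lists had 0.685 and 0.336. Female transcripts lay higher (0.00661, and adjusted p = 0.396 with an estimated correlation, 4 of 6 alone), with an adjusted p of 0.672 without the 3 arrays with yolk signal, where the mean went from 1.692 to 0.09. The 13 probe sets became 2 without those arrays, 0 without the variance trend or the filter, and 0 without conditioned 0 h replicate 2, conditioned 24 h replicate 2 or non-conditioned 0 h replicate 2. They became 5 without conditioned 0 h replicate 1 or conditioned 24 h replicate 1, 3 without non-conditioned 0 h replicate 3 and 21 without conditioned 24 h replicate 3, and none of the 8 named genes past the threshold passed with every array left out.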

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

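The tests of the yolk protein, immune and clock patterns in this part were chosen after the result was seen, the clock criterion was revised after its values were known, and the splits of the arrays were planned.

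Antimicrobial and immune genes (adjusted p = 7.31e-08, and adjusted p = 0.0957 with an estimated correlation) and digestive enzyme genes (adjusted p = 0.00368, and adjusted p = 0.2 with an estimated correlation) stood out because their conditioning effects at 0 h and 24 h differed in a direct test. The digestive list missed the threshold without the 3 arrays with yolk signal (0.487, its mean going from 0.183 to 0.076 with 1 conditioned 24 h array left) and without a filter (0.0996). For the immune list, a single deciding array was argued against at the preset correlation only: with each of the 12 arrays left out, the highest adjusted p was 5.82e-06. With an estimated correlation the list did not pass with all 12 arrays, so the question cannot be put there. A different share of fat body RNA was argued against for the mean, 0.048 in fat body genes outside the list (SE over genes 0.061) against 0.613, to which edin, DptB and PGRP-SC2 add most, but it stays open for typical members, with medians of 0.081 and 0.179. That SE treats genes as independent and does not measure how the share varied between arrays. A shared swing of co-regulated immune genes between few samples stays open, as does a biological effect of conditioning on immunity, which these arrays did not test further.

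The yolk protein signal in 3 conditioned arrays splits both conditioned groups. Arrays made mostly from female heads were argued against, because the male-biased Cyp4d21 in these arrays was never below 94.4% of the mean of the other arrays of its group. RNA from ovaries was argued against, since 0 of 11 eggshell and germline transcripts exceeded 2 times their highest value elsewhere. Yp1 stood out in only 3 of 6 conditioned arrays, so the signal was not shared by every conditioned sample. That count restates how these arrays were picked and is no separate test. A response of some conditioned samples was not tested. A small amount of RNA from female heads may be the source and stays open: fit, a female-biased head transcript, exceeded the arrays of its group without yolk signal in 3 of 3 arrays. This is weak, because in conditioned 0 h replicate 3 fit was 628, within the 162 to 749 of the other 9 arrays.

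As a list, clock transcripts lay lower after conditioning at 0 h (adjusted p = 0.0109, and adjusted p = 0.296 with an estimated correlation), with 12 of 22 values negative and a median of -0.016. There tim, per, vri, Pdp1 and cwo had negative and Clk and cry positive values, of which cwo and vri alone passed the threshold, so that 7 of 7 genes had the direction that 1 shift in the phase of the day predicts (exact two-sided sign test p = 0.0156). The same held for 7 of 7 genes between 0 h and 24 h without conditioning (exact p = 0.0156), for 5 of 7 between conditioned and non-conditioned heads at 24 h (exact p = 0.453) and for 4 of 7 between the times after conditioning (exact p = 1), values that are not independent, since clock genes are co-regulated and the comparisons with 7 of 7 share the non-conditioned 0 h arrays. Collection of those arrays at another phase of the day could explain the comparisons with 7 of 7 and stays open, and the labels give no clock time. The comparison at 24 h does not use the means of those arrays, though they enter its estimate of spread. In it the list also lay lower after conditioning (adjusted p = 0.00472, and adjusted p = 0.312 with an estimated correlation). It missed the threshold without non-conditioned 24 h replicate 1 (adjusted p = 0.0553). Its mean went from -0.062 to -0.043 without the 3 arrays with yolk signal. Between the times after conditioning, where the non-conditioned 0 h arrays again enter only the spread, tim fell by 0.48 ± 0.07, while vri, Pdp1 and cwo had values of 0.06, 0.01 and 0.05. Beyond 2 SE, no gene went against a shift in any comparison, and 4 of 7 went with it at 0 h, none of them Clk or cry, 3 at 24 h, 6 between times without and 2 with conditioning.

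Splits of the 6 arrays of a pairwise comparison into 3 and 3 number 10, too few for a share under 0.05. The real split called 65 probe sets at 0 h, against 0 in the highest other split, 588 between the times without conditioning, against 2, and 526 after conditioning, against 5, so 1 of 10 splits reached the real count in each. At 24 h and for the interaction the real count was 0, which every split reaches whatever the data (10 of 10 and 100 of 100 drawn), so these splits decide nothing. The highest other count was 0 at 24 h and 20 for the interaction. Of 100 splits for the averaged effect, 2 reached 13 or more, the highest other being 16, a share under 0.05. This share speaks only against the absence of any group difference at either time. It cannot show an effect at both times. The splits with 20 and 16 both kept the real groups at 0 h and mixed only the 24 h arrays, and no split that mixed the 0 h arrays called more than 1 in either test. The 8 averaged splits with the real 0 h groups called 0 to 16, so the 24 h arrays move the count too. It fell to 0 without single arrays of either time, rose to 21 without conditioned 24 h replicate 3, and fell to 2 without the arrays with yolk signal, with none of its 8 named genes kept with every array left out.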

How the results depend on the processing

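The fit without the 3 arrays with yolk signal was chosen after the result was seen, and the other tests were planned. No named gene past the threshold changed direction under any setting. No paired analysis was possible because the replicate numbers follow the order of the series and pair no arrays. Where a count moved, the cause was not tested, except that fits without arrays or without a filter have fewer samples or more probe sets tested. Signal over background limits dim genes, for which the offset of 16 shrinks changes.

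Conditioned against non-conditioned at 0 h (65) gave 17 in the # arrays alone (13 shared), 28 without a filter, 8 without trend, 17 without the yolk arrays (13 shared), 146 at an adjusted p of 0.10 and 502 at an unadjusted p of 0.01. Median centring called 58 higher and 27 lower, against 33 and 32. At 24 h, the 0 became 8 in the # arrays, 3 with array weights, 1 with only the groups compared, 2 without the yolk arrays and 102 at an unadjusted p of 0.01. The interaction (0) gave 2 without the title term, 6 in the # arrays, 3 with quantile normalization, 6 with median centring, 4 with offset 64, 1 without a filter, 21 with array weights, 3 without the yolk arrays, 10 at an adjusted p of 0.10 and 221 at 0.01. The time comparison without conditioning (588) gave 246 in the # arrays, 342 without trend, 291 with only its groups, 900 and 982 at the other thresholds, and 517 higher and 165 lower with median centring, against 355 and 233. After conditioning (526) it gave 151 in the # arrays, 334 without a filter, 235 without trend, 976 with array weights, 1095 with only its groups, 18 without the yolk arrays, 852 and 966. The averaged effect (13) gave 20 with quantile normalization, 0 without a filter or trend, 25 with array weights, 2 without the yolk arrays, 27 and 317.

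With each array left out in turn, the counts ran from 14 to 150 at 0 h, 0 to 6 at 24 h, 0 to 8 for the interaction, 297 to 755 and 227 to 729 for the time comparisons without and with conditioning, and 0 to 21 for the averaged effect. Lists past the test ran from 5 to 9, 3 to 6, 2 to 5, 6 to 11, 5 to 7 and 4 to 10 in that order, against 10, 5, 2, 9, 5 and 7. With an estimated correlation every comparison had 0. With fry, 0 lists passed in the conditioning comparisons, the interaction and the averaged effect, and 7 and 4 between times without and with conditioning. Its mixed form, which counts changes in either direction, passed 11 at 0 h, 0 at 24 h, 3 for the interaction, 6 for the averaged effect, and 19 and 18 between times. At 0 h, 1 list passed with quantile normalization, 5 without a filter and 2 without the yolk arrays; the interaction gave 1 without a filter and 1 without the yolk arrays, and the averaged effect 4 with quantile normalization.

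Of 154 named calls, 148 were kept without the title term, 85 in the # arrays, 89 without trend, 111 without a filter and 71 without the yolk arrays. Every reversal was in a gene value that did not pass, or in the oxidative phosphorylation list at 0 h and 24 h, and had no tested cause. In the # arrays EcR, fru and Yp1 at 0 h turned to 0.05, -0.04 and -0.76 and rut over time after conditioning to 0.02. Under median centring dnc turned to 0.01 at 0 h and over time without conditioning, and under quantile normalization the oxidative phosphorylation list at 0 h turned (adjusted p = 0.502). With array weights Hr38 and dnc at 24 h turned to 0.07 and 0.01, tim and CrebB in the interaction to 0.01 and 0.04, and CrebB over time without conditioning to -0.14. Without the yolk arrays EcR, fru and Yp1 at 0 h turned to 0.02, -0.05 and -0.78, and fit, dnc and CrebB at 24 h to -0.24, 0.07 and 0.09. There too per, tim and CrebB in the interaction turned to 0.04, 0.06 and 0.30, dnc and CrebB over time after conditioning to 0.11 and 0.34, and Yp3 and Yp1 in the averaged effect to -0.01 and -0.08.

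Leaving out 1 array turned the following, given as ranges: at 0 h CrebB (-0.16 to 0.08), dnc (-0.06 to 0.06), Hr38 (-0.09 to 0.26), fru (-0.05 to 0.14) and Yp1 (-1.56 to 3.43). At 24 h these were dnc (-0.06 to 0.05), Hr38 (-0.23 to 0.10), rut (-0.18 to 0.04) and the adjusted p of the oxidative phosphorylation list (1.45e-14 to 0.236). In the interaction they were tim (-0.09 to 0.04) and Hr38 (-0.34 to 0.01), and in the averaged effect dnc (-0.04 to 0.02). Over time they were dnc (-0.10 to 0.01), CrebB (-0.10 to 0.22) and Yp1 (-0.22 to 0.06) without conditioning, and rut (-0.07 to 0.01) and dnc (-0.11 to 0.01) after it.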

Other observations

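The list of yolk-bearing arrays was chosen after the result was seen, and the values here are given without explanation.

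Outside the immune and clock genes, the head fat body list changed in both directions over time. Without conditioning, 4 of 19 members rose and 3 fell, or 5 and 3 adjusted over the list alone (list adjusted p = 0.526): the lipid transfer genes Apoltp and Mtp rose by 0.41 and 0.36, while bmm and the lipid droplet gene Lsd-1 fell by 0.61 and 0.48. After conditioning, 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (0.178), with the storage protein gene Lsp2 up by 0.65, AkhR by 0.41 and Acsl by 0.53, and Lsd-1 down by 0.30. Cuticle protein genes followed in both arms with 4 lower and 1 higher of 47 (list adjusted p = 0.0522 without and 0.472 with conditioning), among them Cpr100A by -0.42 and -0.50 and Cpr49Ag by -0.65 and -0.71.

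The eye and glial lists gave single genes that changed alike in both arms. The calcium-binding photoreceptor gene Cpn fell by 0.30 without and 0.34 with conditioning, and ninaD, which serves carotenoid uptake, rose by 0.33 and 0.46. Of the glial genes, bdl fell by 0.23 and 0.35 and wrapper rose by 0.27 and 0.28. The odorant binding protein gene Obp99a rose after conditioning by 0.95 (adjusted p = 0.0487), but only in the 24 h arrays with yolk signal, at 142 and 259, while the other 24 h array had 70.7 and the 0 h arrays 49.2 to 78.8. Without the 3 arrays with yolk signal its value was 0.23 (adjusted p = 0.944). The calcium channel gene cac fell by 0.23.

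In non-conditioned 0 h replicate 3, Acp53Ea reached 149 against 7.8 in the next array, and the sex peptide gene SP 69.4 against 10.7. The probe set with the lowest adjusted p of both time comparisons, 3.39e-12 and 1.2e-12, has no gene symbol.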
